A study of Mus musculus with 11 samples.

How the data were processed

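Messenger RNA was measured on 11 mouse Affymetrix arrays of a leukemic cell line that carries a shortened, mutant Gata1 and was transduced with full-length Gata1 fused to an estrogen receptor. The study describes the cells as synchronized when estradiol was added, without saying how, and as grown with IL3 or Tpo. Which array had which cytokine is not given, so a cytokine difference between treated and untreated arrays is not ruled out. Per the labels, total RNA was extracted with Trizol, cleaned on columns and converted to biotin-labelled cRNA by the standard Affymetrix protocol. The values deposited by the authors are probe set intensities on a linear scale for 45101 probe sets on each array. They are never negative, and array means lie between 145 and 149, so they were taken as already scaled between arrays. The software, background correction and normalization behind them are not given in the sources used here. Every column belongs to a sample of the series, and columns of no sample numbered 0.

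Groups were read from the sample titles and sources. They were untreated cells at 0 h, 24 h and 48 h and estradiol-treated cells at 24 h and 48 h, with 2 arrays each, and treated cells at 8 h with 1 array. No untreated array of 8 h was analysed here, so the 8 h array was set against the 0 h arrays and time and treatment could not be told apart in that comparison. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The small number of arrays limits the precision of every value.

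Probe sets were named from the platform annotation, with symbols updated through the Entrez gene number for 34754 probe sets to a gene table of assembly GRCm38.p6, which served for names alone. Of all probe sets, 34958 had 1 symbol, 932 had several and 9211 had none, and a gene was named only from a probe set with 1 symbol. Each of the 18194 genes was represented by its probe set with the highest mean over the 11 arrays. Genes whose probe set had a mean under the 30th percentile of all probe sets were left out, which removed 3806 and left 14388 tested. Values were analysed as log2(intensity + 16). Differences are therefore on the log2(value + 16) scale, which understates the change of dim genes.

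Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the genes tested and two-sided tests. A gene was called at an adjusted p under 0.05. All 11 arrays entered a single model with a mean for each of the 6 groups, which share a single estimate of the spread with 5 residual degrees of freedom and 13.0 prior degrees of freedom. The lone 8 h array was thereby assumed to vary like the others. Comparisons were estradiol against untreated cells at 24 h, at 48 h and at 8 h, the difference of the effect between 48 h and 24 h, and untreated cells at 24 h and at 48 h against 0 h. A further fit set the 4 treated against the 4 untreated arrays of 24 h and 48 h, without a time term and with 6 residual degrees of freedom.

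A total of 20 gene lists were fixed before the data were examined, and they were tested with camera (limma) at a preset inter-gene correlation of 0.01, with adjustment over the 20 lists. The lists were megakaryocyte and platelet, erythroid, haem synthesis and iron, mast cell with basophil and eosinophil, granulocyte and monocyte, lymphoid, stromal and endothelial, progenitor regulators, E2F targets and DNA replication, and mitosis. The others were cell cycle inhibitors and D cyclins, p53 targets, IGF and mTOR signalling, ribosome biogenesis and MYC targets, interferon response, oestrogen response, apoptosis regulators, glycolysis and hypoxia, cholesterol synthesis, and immediate early and stress. Camera was also run with a correlation estimated from the residuals. The lists hold 506 measured genes, of which 13 belong to several lists.

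Genes named in the text follow a rule fixed before the data were examined. For the estradiol effect at 24 h and 48 h it took the 10 called genes with the largest difference each way for which both treated arrays lay beyond both control arrays. For the 8 h effect, the difference between times and the untreated comparisons it took the 5 largest each way. From each list it took up to 4 members with the smallest adjusted p at 48 h. A set of regulators and lineage genes was always included, of which Mpl and Hbb-b1 were not analysed here because no probe set with a single symbol named them. Genes outside the rule are said to be so.

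The fit and the list test were first tested on simulated data with 14388 genes, in which 200 genes were changed. Each gene's spread was the one that limma, with its prior, had estimated from the real arrays. For the 24 h comparison, 47 of 100 genes changed by 0.5 on the log2 scale were recovered and 88 of 100 changed by 1, with 15 false calls. Recovery at those sizes was 54 and 94 for the 48 h comparison, 28 and 82 for 8 h, 20 and 76 for the difference between times, 47 and 91 for untreated cells at 24 h, and 50 and 95 for untreated cells at 48 h. For the comparison over both times it was 70 and 98. A simulated shift of 0.2 in the megakaryocyte and platelet list at 24 h was called, and 0 of the 19 other lists were. Simulated genes varied independently, so this cannot show how often the list test errs when members of a list vary together.

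Alternatives set before the data were examined were quantile normalization, centring on array medians, a pseudocount of 1 or 64, no filter or a filter at the 50th percentile, the mean of all probe sets of a gene, a prior without the intensity trend, a robust prior, and the replicate number as a block. Each array was also left out in turn, fits were limited to the 4 arrays of a single time, time was added as a covariate to the fit over both times, and a 2-fold threshold was added to overlaps of calls. Alternatives added after the data had been seen were the 8 h array set against untreated 24 h arrays, and fits without the 0 h and 8 h arrays. Gene families read from the start of their symbols were likewise added afterwards.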

Results

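The cells studied were a mouse leukemia of the M7 (megakaryoblastic) type that arose from fetal progenitors with a Gata1 mutation and so makes only a short form of GATA1, a transcription factor that drives megakaryocyte and red cell development. A full-length Gata1 fused to an estrogen receptor had been introduced into them, and beta-estradiol in the medium activates that fusion protein. Expression was measured on 11 arrays: 2 each of untreated cells at 0 h, 24 h and 48 h, 2 each of estradiol-treated cells at 24 h and 48 h, and 1 of cells treated for 8 h. The comparisons ask which genes change when full-length GATA1 becomes active, and how that response develops over time. Levels are probe set intensities, given as mean ± SD with n = 2 unless stated otherwise, and differences are on the log2(value + 16) scale with their SE.

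Gata1 RNA, the gene carried by the fusion construct, was level on all arrays. It lay between 781 and 859, and averaged 813 ± 22.4 in untreated and 785 ± 3.93 in treated cells at 48 h (difference -0.049 ± 0.063). Whether the probe set reads the endogenous transcript, the introduced one or both was not tested. Estradiol acts on the fusion protein, so this level does not read its activation. Esr1, the estrogen receptor gene, stayed between 27.2 and 47.7. Array medians lay between 37.9 and 40.5, and replicates of a group correlated at 0.983 to 0.987 across the 14388 genes tested. Arrays of different groups correlated at 0.967 to 0.988, and replicates were distinct, sharing at most 8 identical values of 45101. Signal at the 18S ribosomal RNA control probe sets varied more and was lower on all 48 h arrays than on the 0 h arrays. Its mean log2 values were 6.84 and 7.0 at 0 h, 7.28 on the 8 h array, and 7.48 and 6.3 in untreated cells at 24 h and 6.02 and 6.18 in treated cells at 24 h. At 48 h they were 5.78 and 5.53 in untreated and 5.50 and 5.89 in treated cells.

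After 24 h of estradiol, the platelet genes Ppbp, Pf4 and Itgb3 were among the 10 largest rises. Ppbp, which encodes the granule chemokine platelet basic protein, went from 44.8 ± 1.83 to 776 ± 88.0, a rise of 3.70 ± 0.14. Pf4, platelet factor 4, rose by 2.55 ± 0.056, from 1028 ± 34.7 to 6096 ± 195. Itgb3, the beta chain of the platelet fibrinogen receptor, rose by 2.05 ± 0.18, whereas its partner Itga2b differed by -0.11 ± 0.074 and was not called. The adhesion protein gene Vcl (vinculin) rose by 1.58 ± 0.080, the haem-linked mitochondrial transporter gene Abcb10 by 1.61 ± 0.10, and P2ry1, a platelet ADP receptor gene, by 1.28 ± 0.087. Cxcl3, a chemokine gene, rose by 2.85 ± 0.17, Ephx2 (soluble epoxide hydrolase) by 2.51 ± 0.14, Tmem158 by 1.91 ± 0.11 and the adaptor gene Sla by 1.60 ± 0.084. Csf2rb2, which rose by 1.59 ± 0.058, encodes a cytokine receptor chain nearly identical in sequence to Csf2rb, itself up by 1.14 ± 0.058, so the share of each is uncertain.

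The genes that fell most at 24 h included Bex6, by -1.74 ± 0.13, from 274 ± 28.5 to 71.7 ± 16.4. Prtn3, the neutrophil protease proteinase 3, changed by -1.16 ± 0.17, and Pglyrp1, a peptidoglycan-binding protein of granulocytes, by -0.90 ± 0.12. Greb1, an estrogen-induced gene of breast cells, fell from 614 ± 43.4 to 298 ± 27.7 (-1.0 ± 0.085). Further falls were -1.30 ± 0.24 in Ms4a4b, -0.98 ± 0.14 in Ms4a6b, -0.96 ± 0.12 in Myl10, -1.27 ± 0.33 in Ly6f, -1.17 ± 0.24 in Caln1 and -1.02 ± 0.24 in the potassium channel gene Kcna7. Ms4a4b, Ly6f, Caln1 and Kcna7 were dim, at 48.1 ± 15.6, 37.4 ± 22.6, 48.5 ± 2.56 and 57.4 ± 5.73 in untreated cells. Among regulators, Myb, a progenitor transcription factor, fell by 0.65 ± 0.087 on the log2 scale, Myc by 0.56 ± 0.069, Sox4 by 0.52 ± 0.078, and Spi1, which encodes the myeloid factor PU.1, by 0.42 ± 0.079. Zfpm1, the gene of the GATA1 partner FOG1, rose by 0.47 ± 0.059, and Lmo2, part of the same complexes, by 0.74 ± 0.076. Gata2 (-0.14 ± 0.074), Ikzf1 (0.23 ± 0.079), Kit (-0.23 ± 0.11), Klf1 (0.15 ± 0.089), Nfe2 (-0.12 ± 0.057), Fli1 (0.30 ± 0.12), E2f1 (0.075 ± 0.11) and Igf1r (0.23 ± 0.077) were not called at 24 h. Another Gata2 probe set, nearly as bright (mean log2 9.33 against 9.44), differed by -0.40 and was not tested, so a fall of Gata2 stays open.

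In all, 415 of 14388 genes were called at 24 h, 285 higher and 130 lower, of which 39 and 7 changed at least 2-fold. Of the 47 named genes called, 24 had several probe sets above the intensity filter, and Cpox and Sox4 had one of opposite sign. Below the filter, so did Caln1 and Psmb8. With a prior that ignores the intensity trend 190 genes were called, and without treated replicate 2 of 24 h 257 were.

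**Figure D1:**
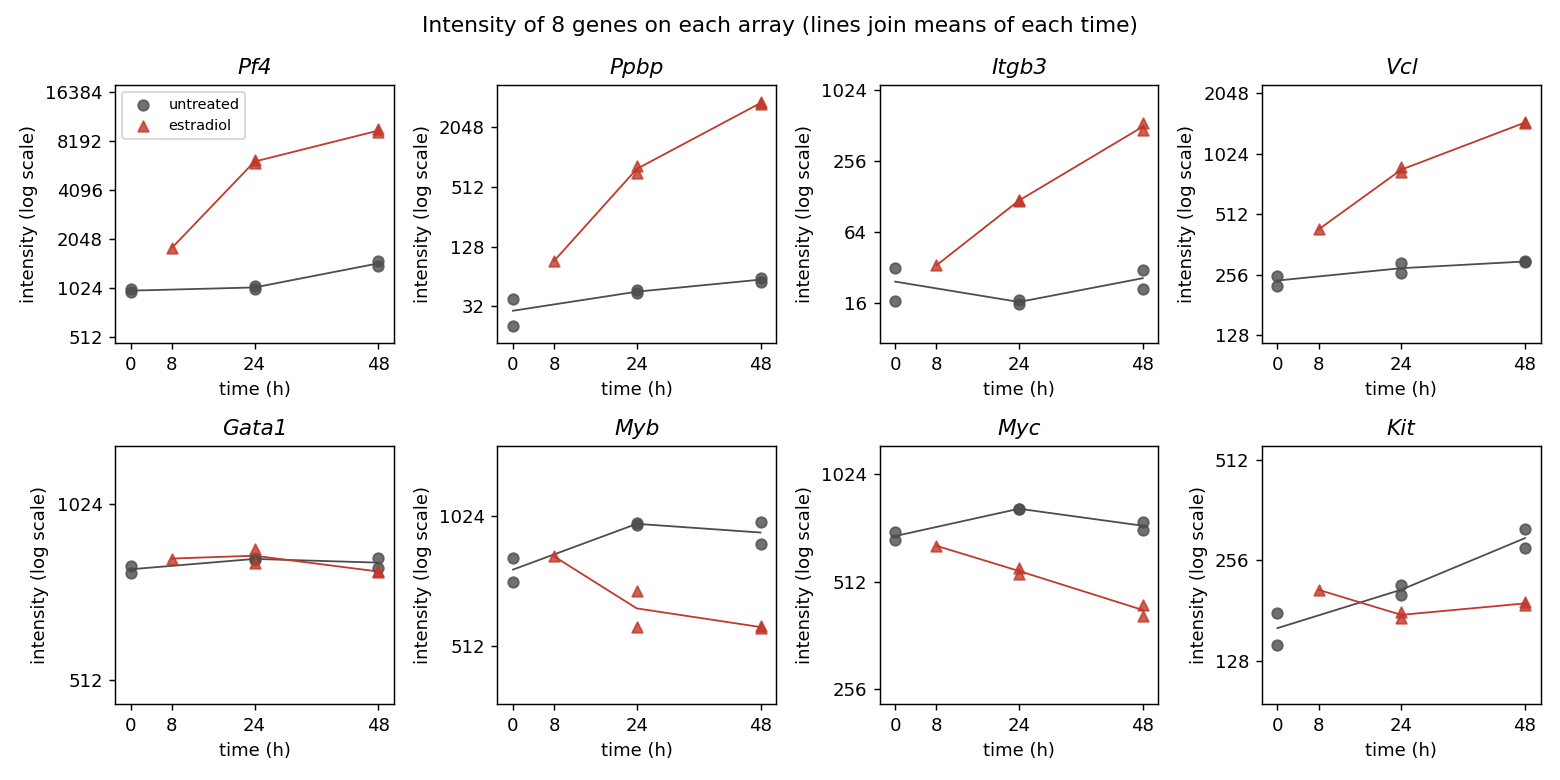
Intensity on each array (log axis) against hours, with untreated cells as circles, estradiol-treated cells as triangles and lines joining the means of each time. Ppbp reached 3585 after 48 h of estradiol against 59.4 in untreated cells, and Gata1 stayed between 781 and 859 on every array.

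Of the 29 measured genes of the megakaryocyte and platelet list, 10 rose at 24 h, none fell and 19 were not called, with 14 up and 1 down when adjusted over the list alone. Besides Ppbp, Pf4, Itgb3 and P2ry1, these included Plek (pleckstrin, 0.61 ± 0.059) and the granule secretion gene Rab27b (0.61 ± 0.10). The list's median was 0.27 (camera adjusted p = 2.19e-15, and adjusted p = 0.0182 with an estimated correlation), the sole list at 24 h whose call held with an estimated correlation. In the haem synthesis and iron list, 4 of 20 genes rose and none fell (8 up and 2 down when adjusted over the list alone), among them Abcb10, Cpox (0.99 ± 0.11) and Alad (0.61 ± 0.072), enzymes of the pathway in the case of Cpox and Alad. That list's median was 0.19 (camera adjusted p = 6.25e-06, adjusted p = 0.122 with an estimated correlation). Cell cycle inhibitors and D cyclins had 3 of 20 genes up and none down (7 up and 2 down when adjusted over the list alone), with the antiproliferative genes Btg2 (0.84 ± 0.067) and Btg1 (0.52 ± 0.078) among them. Their median was 0.18 (camera adjusted p = 0.00129, adjusted p = 0.313 with an estimated correlation), while the inhibitor gene Cdkn1a differed by 0.39 ± 0.13 and was not called.

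Ribosome biogenesis and MYC target genes moved the other way at 24 h: 4 of 44 fell, including Nhp2 (-0.38 ± 0.075) and Nop56 (-0.30 ± 0.068), none rose, and 6 fell when adjusted over the list alone. The list's median was -0.13 (camera adjusted p = 5.5e-09, adjusted p = 0.122 with an estimated correlation). Among granulocyte and monocyte genes, 6 of 22 fell, 6 also when adjusted over the list alone, and none rose, with Cd68 (-0.85 ± 0.12), Prtn3, the oxidase subunit gene Ncf1 (-0.52 ± 0.084) and Spi1 among them. That list's median was 0.0051 although its mean was -0.16 and camera's direction was down (adjusted p = 0.00105, adjusted p = 0.0957 with an estimated correlation). The mast cell, basophil and eosinophil list had 3 genes up and 1 down of 20, the same counts when adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.122 with an estimated correlation). Its risers were the cytokine gene Il6 (1.31 ± 0.091), Csf2rb and Rab27b, while the mast cell protease gene Cpa3 differed by -0.27 ± 0.22 and was not called. Cholesterol synthesis had 1 of 21 genes up, Msmo1 (0.34 ± 0.090), and 1 when adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.313 with an estimated correlation). The mast cell call ended with a filter at the 50th percentile (adjusted p = 0.065). Without treated replicate 1 of 24 h, the mast cell and cholesterol calls ended (adjusted p = 0.0897 and 0.0855), as they did without untreated replicate 2 of 24 h (0.0678 and 0.079). E2F targets and mitosis genes did not pass at 24 h, with medians of -0.051 and -0.046 (adjusted p = 0.144 and 0.26). Under the alternatives set beforehand, E2F targets gained a call in 2 of 14 settings and mitosis in 1 of 14. Beside these groups, 18S log2 signal was 6.02 and 6.18 on the treated and 7.48 and 6.3 on the untreated arrays of 24 h.

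**Figure D2:**
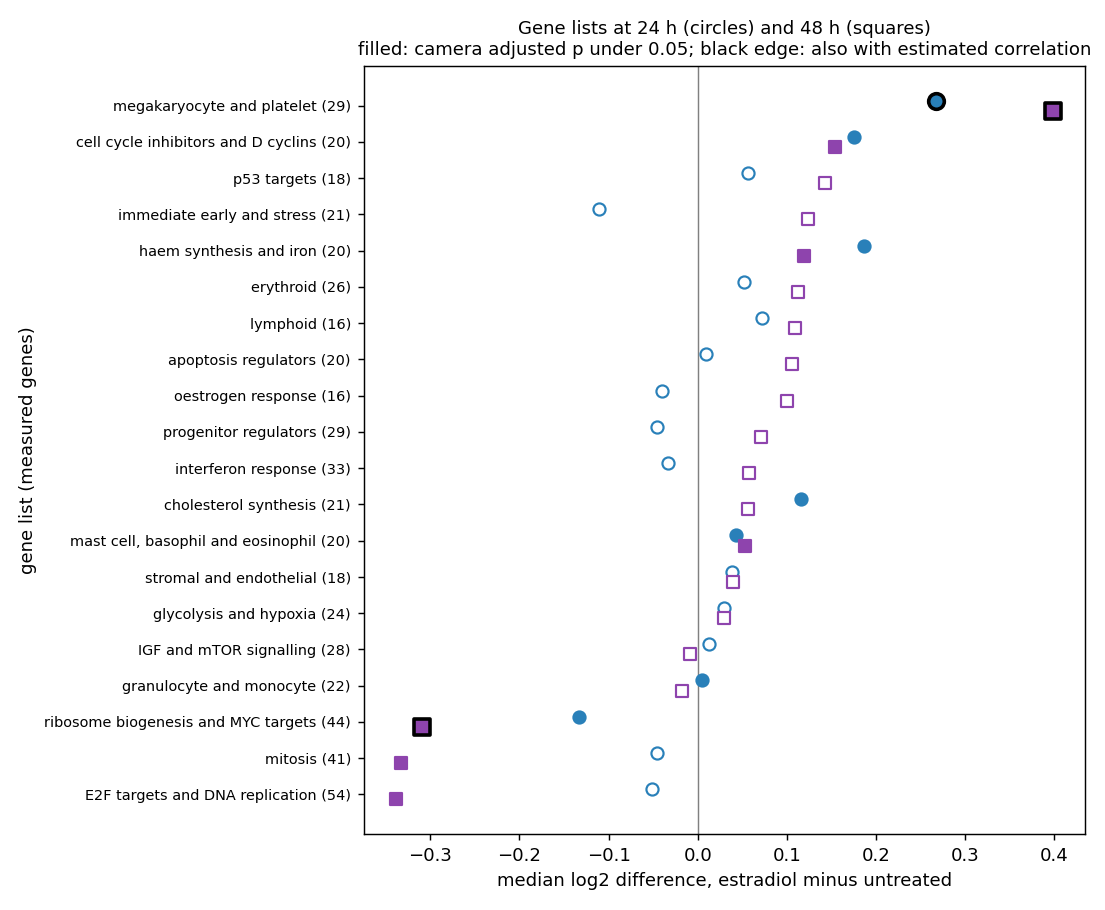
Median log2 difference between estradiol-treated and untreated cells for each of the 20 gene lists, at 24 h (circles) and 48 h (squares), with the number of measured genes in brackets; filled marks passed camera and black edges also passed with an estimated correlation. The megakaryocyte and platelet list stood highest at both times, at 0.27 and 0.40, and E2F targets stood lowest at 48 h, at -0.34.

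After 48 h of estradiol the platelet genes stood higher still. Ppbp reached 3585 ± 76.1 against 59.4 ± 3.88 in untreated cells (5.58 ± 0.14), Pf4 reached 9450 ± 251 against 1445 ± 64.7 (2.70 ± 0.056), and Itgb3 reached 499 ± 48.0 against 26.0 ± 6.69 (3.62 ± 0.18). Itga2b was called at this time, at 1559 ± 47.0 against 1225 ± 15.7 (0.34 ± 0.074), as was the megakaryocyte transcription factor gene Fli1 (0.39 ± 0.12). Cxcl3 rose by 4.02 ± 0.17, Ephx2 by 3.65 ± 0.14, Tmem158 by 2.68 ± 0.11, Sla by 2.36 ± 0.084, Il6 by 2.27 ± 0.091 and Vcl by 2.24 ± 0.080. Bbip1, a gene of the ciliary BBSome complex, rose by 2.01 ± 0.082 at its brightest probe set, while the other pair differed by 0.017 and -0.15. Apart from the dim genes Havcr1 and Cntn4, the largest falls were in Bex6 (-1.79 ± 0.13), Cmtm7 (-1.22 ± 0.071), the macrophage gene Cd68 (-1.20 ± 0.12), Myl10 (-1.18 ± 0.12) and Sh2b3, an adaptor that restrains cytokine receptor signalling (-1.15 ± 0.15). Further falls were -1.04 ± 0.10 in B3gnt5, -1.02 ± 0.087 in the cytoskeletal linker gene Plec and -1.0 ± 0.085 in the fatty acid binding gene Fabp5. Havcr1 (-1.16 ± 0.28) and Cntn4 (-1.12 ± 0.24) also fell but were dim, at 39.5 ± 8.47 and 40.9 ± 4.62 in untreated cells.

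Among single regulators at 48 h, Myc fell from 734 ± 25.2 to 427 ± 21.6 (-0.76 ± 0.069) and Myb from 938 ± 80.2 to 566 ± 5.62 (-0.71 ± 0.087). Kit, the stem cell factor receptor gene, was at 298 ± 27.2 in untreated and 190 ± 3.50 in treated cells (-0.60 ± 0.11). Untreated Kit was at 160 ± 25.4 at 0 h and 209 ± 9.56 at 24 h, so treated Kit did not fall below its 0 h level. Its other probe set differed by -0.30. Sox4 (-0.66 ± 0.078) and Spi1 (-0.49 ± 0.079) fell, whereas Lmo2 (0.89 ± 0.076), Zfpm1 (0.50 ± 0.059) and the GATA1 target Gfi1b (0.57 ± 0.12) rose. Btg2 rose by 1.42 ± 0.067 and Btg1 by 0.91 ± 0.078, E2f2 and Cdk4 fell by 0.94 ± 0.10 and 0.60 ± 0.071 on the log2 scale, and E2f1 rose by 0.41 ± 0.11. Not called were Gata2 (-0.15 ± 0.074), Ikzf1 (0.071 ± 0.079), Klf1 (-0.22 ± 0.089), Nfe2 (-0.11 ± 0.057), Igf1r (0.11 ± 0.077), Igf2 (-0.080 ± 0.15), Cdkn1a (0.042 ± 0.13), Cpa3 (-0.31 ± 0.22) and Esr1 (0.28 ± 0.18). The other Gata2 probe set, nearly as bright, differed by -0.52 and was not tested, so these values do not settle whether Gata2 fell. The red cell genes Hba-a1 (0.048 ± 0.16) and Alas2 (0.35 ± 0.23) were not called either, at 87.1 ± 7.07 and 30.9 ± 1.18 in treated cells. Hba-a1 was read by a single probe set and Hbb-b1 was not analysed, so these values do not settle whether globin RNA changed.

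At 48 h 1490 genes were called, 753 higher and 737 lower, of which 85 and 10 changed at least 2-fold. Of the 87 named genes called, 52 had several probe sets above the intensity filter and 9 had one of opposite sign: Bbip1, Havcr1, Cpox, Sox4, Cdk6, Mdm2, Foxo1, Akt2 and Bid. Below the filter, so did Cntn4, Cdt1, Aurka, Grb10, Klf6 and E2f1. The count was 620 with a prior that ignores the intensity trend, and it was 845 and 881 without untreated replicate 1 or 2 of 48 h and 899 and 808 without treated replicate 1 or 2.

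In the megakaryocyte and platelet list, 16 of 29 genes rose at 48 h, 1 fell and 12 were not called (19 up and 1 down when adjusted over the list alone), with a median of 0.40 (camera adjusted p = 1.34e-20, and adjusted p = 0.00913 with an estimated correlation). P2ry1 rose by 1.88 ± 0.087, Plek by 1.22 ± 0.059 and Rab27b by 0.90 ± 0.10. Of 44 ribosome biogenesis and MYC target genes, 25 fell and none rose (33 down when adjusted over the list alone), including Nhp2 (-0.68 ± 0.075), Nop56 (-0.56 ± 0.068) and the polyamine enzyme gene Srm (-0.55 ± 0.073). Their median was -0.31 (camera adjusted p = 2.48e-20, and adjusted p = 0.0417 with an estimated correlation). Of 54 E2F target and DNA replication genes, 33 fell, 2 rose and 19 were not called (40 down and 2 up when adjusted over the list alone). The replication licensing gene Cdt1 fell from 423 ± 9.74 to 264 ± 5.97 (-0.65 ± 0.076), the helicase subunit gene Mcm3 by 0.49 ± 0.071 and the clamp gene Pcna by 0.37 ± 0.052 on the log2 scale. The median was -0.34 (camera adjusted p = 4.21e-18, adjusted p = 0.105 with an estimated correlation). Of 41 mitosis genes, 21 fell and none rose (30 down when adjusted over the list alone), with the mitotic kinase genes Aurkb (-0.49 ± 0.099), Aurka (-0.47 ± 0.089) and Plk1 (-0.43 ± 0.084) and the kinetochore gene Nuf2 (-0.54 ± 0.098) among them. Their median was -0.33 (camera adjusted p = 6.22e-17, adjusted p = 0.0791 with an estimated correlation). On the same arrays 18S log2 signal was 5.50 and 5.89 in treated and 5.78 and 5.53 in untreated cells.

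Smaller shifts at 48 h passed camera in 3 further lists, and none of them held with an estimated correlation. Haem synthesis and iron had 4 genes up and 1 down of 20 (7 up and 3 down when adjusted over the list alone), with Abcb10 at 1.89 ± 0.10 and Cpox at 0.62 ± 0.11 (camera adjusted p = 0.0195, adjusted p = 0.309 with an estimated correlation). Cell cycle inhibitors and D cyclins had 6 up and 2 down of 20 (6 up and 3 down when adjusted over the list alone), and the falls were in the kinase genes Cdk4 and Cdk6 (-0.35 ± 0.057), which drive rather than inhibit the cycle (camera adjusted p = 0.0201, adjusted p = 0.409 with an estimated correlation). The mast cell, basophil and eosinophil list had 5 up and 2 down of 20, the same counts when adjusted over the list alone, with Il6, Csf2rb (1.45 ± 0.058), Rab27b and the granule proteoglycan gene Srgn (0.34 ± 0.046) up and Kit down (camera adjusted p = 0.0236, adjusted p = 0.138 with an estimated correlation). Without untreated replicate 2 of 48 h the calls of all 3 ended (adjusted p = 0.0554 for haem, 0.0554 for inhibitors and 0.0646 for mast cell, whose median turned to -0.0030). With a prior that ignores the intensity trend the haem and mast cell calls ended (adjusted p = 0.0571 and 0.143), as did the mast cell call without a filter on dim genes (0.0897).

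The remaining lists did not pass at 48 h. Erythroid genes had 4 up and 3 down of 26 (5 and 3 when adjusted over the list alone), with the carbonic anhydrase gene Car2 up by 0.86 ± 0.053 and Car1 down from 2007 ± 46.2 to 1212 ± 6.79 (camera adjusted p = 0.45). Granulocyte and monocyte genes had 4 down of 22, 4 also when adjusted over the list alone, namely Cd68, Prtn3 (-0.78 ± 0.17), Ncf1 (-0.62 ± 0.084) and Spi1 (camera adjusted p = 0.165). Progenitor regulators had 9 up and 7 down of 29 (10 and 7 when adjusted over the list alone; camera adjusted p = 0.666). Of markers of other cell types, 1 of 16 lymphoid genes rose, Cd3g (0.46 ± 0.14), and none when adjusted over the list alone (adjusted p = 0.281). By either count, 1 of 18 stromal and endothelial genes rose, the receptor kinase gene Tek (1.18 ± 0.10; adjusted p = 0.53). Interferon response genes had 6 up and 2 down of 33 (8 and 2 when adjusted over the list alone), with Ifit1 (0.54 ± 0.097) and Usp18 (0.36 ± 0.083) up and the immunoproteasome gene Psmb8 down (-0.52 ± 0.080; adjusted p = 0.165). Apoptosis regulators had 3 up of 20, Bcl2l11 (1.1 ± 0.14), Bid (0.48 ± 0.11) and Bcl2 (0.30 ± 0.077), and 3 up and 1 down when adjusted over the list alone (adjusted p = 0.13). Bcl2's next brightest probe set differed by 0.025.

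Oestrogen response genes had 3 up and 2 down of 16, the same counts when adjusted over the list alone (camera adjusted p = 0.57 at 48 h). Greb1 (-0.88 ± 0.085) and Sgk3 (-0.46 ± 0.072) fell, while Esr2, the second estrogen receptor gene, rose from 13 ± 1.43 to 62.4 ± 7.55 (1.44 ± 0.23), and Xbp1 by 0.32 ± 0.087. The p53 target list had 2 up and 1 down of 18 (4 and 3 when adjusted over the list alone; adjusted p = 0.168), with Btg2 and Mdm2 (0.31 ± 0.076) up and Gtse1 (-0.80 ± 0.18) down. Mdm2 had the opposite sign with the mean of its probe sets, at -0.068. IGF and mTOR signalling genes had 3 up, Igf2r (0.64 ± 0.13), Grb10 (0.61 ± 0.15) and Foxo1 (0.60 ± 0.15), and Akt2 down (-0.36 ± 0.098) of 28, with 4 and 1 when adjusted over the list alone. That list's median was -0.0089 although its mean was 0.063 and camera's direction was up (adjusted p = 0.45). Glycolysis and hypoxia genes had 1 up and 4 down of 24 (1 and 5 when adjusted over the list alone), with Hk1 (-0.30 ± 0.069), Pgk1 (-0.20 ± 0.053) and Gapdh (-0.19 ± 0.049) down and Pkm up (0.25 ± 0.069). Its median was 0.029 and its mean 0.012, whereas camera's direction was down (adjusted p = 0.53). Cholesterol synthesis had 2 up of 21, Fads2 (0.38 ± 0.074) and Msmo1 (0.32 ± 0.090), and 4 when adjusted over the list alone (adjusted p = 0.115). Immediate early and stress genes had 3 up and 2 down of 21 by either count, with Klf6 up (0.80 ± 0.13) and Ier3 (-0.52 ± 0.098) and Trib3 (-0.44 ± 0.12) down (adjusted p = 0.267).

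The effect of estradiol was larger at 48 h than at 24 h for several platelet genes, by the test of the difference itself. Ppbp's effect was larger at 48 h by 1.88 ± 0.19, Itgb3's by 1.57 ± 0.25, P2ry1's by 0.60 ± 0.12 and Plek's by 0.60 ± 0.084, while Pf4's did not differ detectably between these arrays. Btg2's was larger by 0.58 ± 0.094. Il6's was larger by 0.97 ± 0.13, with lower untreated cells (290 ± 22.4 at 24 h and 165 ± 18.8 at 48 h) beside treated cells at 742 ± 65.3 and 855 ± 12.2. Effects also differed upward for Cxcl3 (1.17 ± 0.24), the glutamate receptor gene Grm2 (1.42 ± 0.28) and the vesicle protein gene Syngr1 (1.26 ± 0.24). Grm2 was not called at 24 h, at 26.3 ± 10.1 with estradiol against 50.9 ± 13 without, and rose at 48 h. Untreated Syngr1 was at 156 ± 35.3 at 24 h and 76.6 ± 9.01 at 48 h, and untreated Large2 at 19.4 ± 1.79 and 52.0 ± 3.96, so untreated cells make up part of both differences. Effects were lower at 48 h for Large2 (-1.53 ± 0.28), the growth factor receptor gene Fgfr4 (-1.04 ± 0.19), Usp31 (-0.77 ± 0.16), the nucleolar gene Lyar (-0.59 ± 0.11), the Myc-induced gene Cdca7 (-0.57 ± 0.12) and Car1 (-0.40 ± 0.086). Untreated cells make up part of the differences of Fgfr4 (76.3 ± 18.8 at 24 h and 123 ± 11.6 at 48 h) and Car1 (1599 ± 11.1 and 2007 ± 46.2) too. Other probe sets above the intensity filter did not show the differences of Syngr1, Fgfr4 or Usp31. The brightest of them differed by -0.018 at 24 h and -0.090 at 48 h for Syngr1, -0.17 and -0.14 for Fgfr4, and 0.086 and 0.067 for Usp31. Plek's other probe sets showed a smaller step. The brighter differed by 0.73 at 24 h and 0.98 at 48 h, and the dimmer by 0.80 and 1.08. The megakaryocyte and platelet list shifted further up, by a median of 0.21 with 6 of 29 genes called and 11 when adjusted over the list alone (camera adjusted p = 1.62e-11, and adjusted p = 0.0392 with an estimated correlation). E2F targets shifted down by a median of -0.29, with 1 gene called and 17 when adjusted over the list alone (camera adjusted p = 1.88e-18, adjusted p = 0.0868 with an estimated correlation). Mitosis genes shifted by -0.24, with none called and 11 when adjusted over the list alone (camera adjusted p = 4.29e-16, adjusted p = 0.0868 with an estimated correlation). Ribosome biogenesis genes shifted by -0.17, with 1 called and 8 when adjusted over the list alone (camera adjusted p = 8.05e-10, adjusted p = 0.0868 with an estimated correlation).

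In all 54 genes differed in effect between the times, 40 upward and 14 downward. With a prior that ignores the intensity trend limma called none, while 1246 genes had an unadjusted p under 0.05. Chance alone would give 0.05 of the 14388 tested. Limma called 82 with quantile normalization and 18 with the mean of all probe sets of a gene. Leaving out a single array gave 33 without untreated replicate 2 of 24 h, 23 and 28 without untreated replicate 1 or 2 of 48 h, and 16 and 20 without treated replicate 1 or 2 of 48 h.

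**Figure D3:**
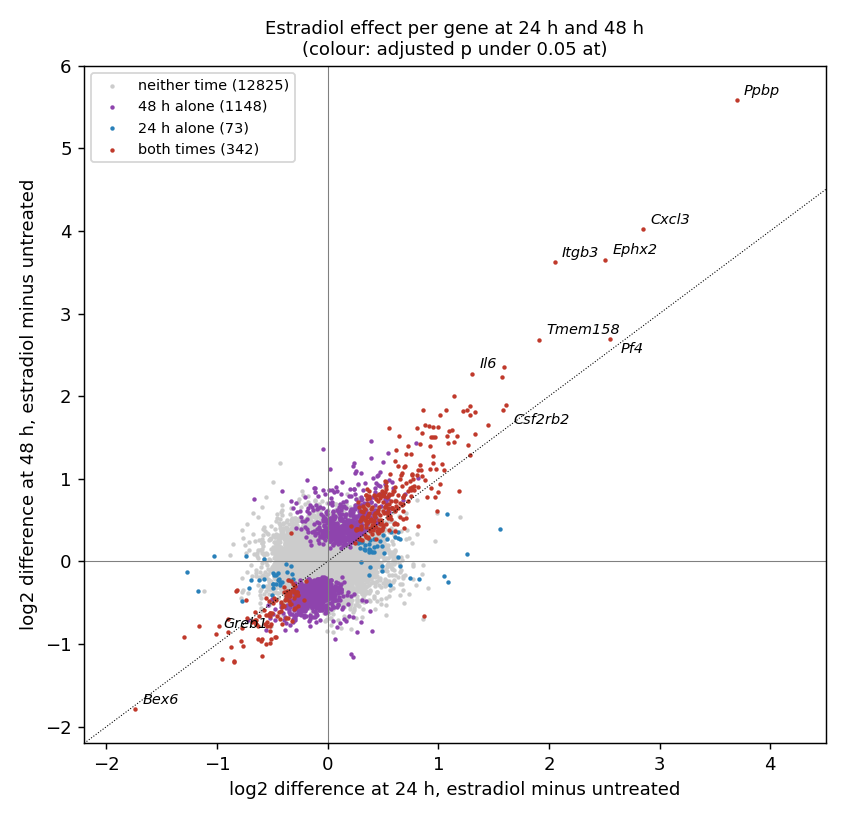
Log2 difference between estradiol-treated and untreated cells for each of 14388 genes at 24 h (horizontal) and 48 h (vertical), coloured by whether it passed at both times, one or neither, with a dotted line of equal effects. Ppbp, Cxcl3, Ephx2 and Itgb3 lie above the line, and Pf4 lies close to it at 2.55 and 2.70.

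Most genes called at 24 h were called again at 48 h, in comparisons that have no array in common but share each gene's estimate of the spread. Genes with a small estimated spread are favoured at both times, so the overlaps expected of independent lists may be too low. Of the 285 genes higher at 24 h, among them Pf4, Ppbp and Vcl, 242 were also among the 753 higher at 48 h, where 14.9 would be expected of independent lists. Of the 130 lower at 24 h, among them Myb, Myc and Bex6, 98 were also among the 737 lower at 48 h, against 6.66 expected, and 1 gene in each direction was called with the opposite sign. Across all genes, which are not independent replicates, the effects correlated at r = 0.43. Requiring a 2-fold change as well left 32 shared genes.

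At 8 h, set against the 0 h arrays, Ppbp was already higher, at 91.9 against 28.8 ± 12.2 (1.30 ± 0.17), as were Pf4 (0.86 ± 0.069), P2ry1 (0.91 ± 0.11) and Abcb10 (0.92 ± 0.12). Tmem158 (1.21 ± 0.13), the fibrinogen-like gene Fgl2 (1.08 ± 0.13), Csf2rb2 (1.04 ± 0.071) and the actin-regulated cofactor gene Mrtfa (0.99 ± 0.13) were the other largest rises, and Btg2 rose by 0.57 ± 0.082. Myb and Myc were not called at 8 h. Falls were led by Ms4a4b (-1.68 ± 0.29), the junction gene Jup (-1.30 ± 0.30), the interferon-induced gene Ifit3 (-1.29 ± 0.16), Fat1 (-1.22 ± 0.29) and Zswim6 (-1.21 ± 0.25). Jup, Fat1 and Zswim6 were dim, at 53.9 ± 21.2, 33.8 ± 7.12 and 71.0 ± 20.3 at 0 h. On the lone 8 h array they read 11.7, 5.23 and 21.0. With estradiol at 24 h they stood at 90.5 ± 4.93, 27.2 ± 11.9 and 71.0 ± 1.73. Of the megakaryocyte and platelet list, 4 of 29 genes rose and none fell, with 7 up when adjusted over the list alone (median 0.17, camera adjusted p = 7.19e-07, adjusted p = 0.11 with an estimated correlation). Haem synthesis and iron had 5 of 20 genes up by either count (adjusted p = 1.28e-05, adjusted p = 0.216 with an estimated correlation). Cell cycle inhibitors and D cyclins had 1 of 20 up, and 4 when adjusted over the list alone (adjusted p = 2.1e-06, adjusted p = 0.248 with an estimated correlation). Erythroid genes had 1 of 26 up, and 3 when adjusted over the list alone (adjusted p = 0.0309, adjusted p = 0.248 with an estimated correlation). Of 33 interferon response genes 14 fell and none rose, with 24 down when adjusted over the list alone (median -0.36, adjusted p = 9.08e-38, adjusted p = 0.11 with an estimated correlation). E2F targets, mitosis and ribosome biogenesis genes had none called against 0 h by either count. Set against the untreated arrays of 24 h instead, the 8 h medians were 0.027 for interferon response (adjusted p = 0.413) and 0.021 for megakaryocyte and platelet with 12 of 29 genes negative (adjusted p = 0.00234, adjusted p = 0.208 with an estimated correlation). Haem synthesis and iron had 0.12 (adjusted p = 0.00116, adjusted p = 0.215 with an estimated correlation). The calls of cell cycle inhibitors and D cyclins (adjusted p = 0.0528) and of erythroid genes (adjusted p = 0.253) ended there. Lists that passed there but not against 0 h were progenitor regulators (median -0.078, adjusted p = 0.00266), granulocyte and monocyte (-0.094, 0.0259), E2F targets (-0.034, 0.0288) and mitosis (-0.056, 0.0298) downward. Mast cell, basophil and eosinophil (0.056, 0.0288) and cholesterol synthesis (0.089, 0.0453) passed upward, and none of these 6 held with an estimated correlation, the lowest adjusted p being 0.208.

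A total of 143 genes were called at 8 h, 81 higher and 62 lower. Of the 81, 62 were also higher at 24 h (1.60 expected of independent lists), Pf4, Ppbp and Tmem158 among them, and of the 62 lower, 12 were also lower at 24 h (0.560 expected), with r = 0.20 across genes. At 48 h, 63 of the 81 were also higher and 1 was lower. Of the 62 lower at 8 h, 13 were lower at 48 h and 11 were higher, Ifit1 and Usp18 among the latter, and 32 kept their sign. These overlaps rest on a lone treated 8 h array, whose spread was taken from the other groups. The comparisons also share each gene's estimate of the spread, so the lists are not fully independent. With a prior that ignores the intensity trend, 1030 genes had an unadjusted p under 0.05 at 8 h. Chance alone would give 0.05 of the 14388 tested, and limma called none after adjustment. The count was 78 with the mean of all probe sets of a gene, 51 without untreated replicate 1 of 0 h and 54 against the untreated arrays of 24 h, where Ifit1 and Usp18 had the opposite sign (0.14 and 0.066).

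With the 4 treated arrays of 24 h and 48 h set against the 4 untreated ones, 848 genes were called, 528 higher and 320 lower. The megakaryocyte and platelet list had 13 up and 1 down of 29, with Ppbp and Pf4 among those up (19 and 1 when adjusted over the list alone; camera adjusted p = 3.5e-15, adjusted p = 0.148 with an estimated correlation). Ribosome biogenesis and MYC targets had 11 of 44 down, Nhp2 and Nop56 among them, and 24 when adjusted over the list alone (adjusted p = 1.31e-15, adjusted p = 0.178 with an estimated correlation). The count was 468 with a prior that ignores the intensity trend and 561 without treated replicate 1 of 48 h.

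Untreated cells also changed with time, and interferon response genes fell. Camera called 7 of 20 lists at 24 h, 5 up and 2 down, and 8 at 48 h, 5 up and 3 down. Not all of them are named here, and 0 held with an estimated correlation at either time. Ifit3 was at 726 ± 103 at 0 h, 313 ± 42.8 at 24 h and 231 ± 39.7 at 48 h, changes of -1.17 ± 0.13 and -1.59 ± 0.13. The interferon-induced GTPase gene Iigp1 fell by -1.07 ± 0.14 and -1.55 ± 0.14, and Ifnb1, which encodes interferon beta, by -1.04 ± 0.18 and -1.54 ± 0.18. Ms4a4b fell by -1.25 ± 0.24 and -1.91 ± 0.24, Ptpn13 by -1.46 ± 0.28 at 48 h, and Gm9706 by -1.12 ± 0.15 at 24 h, whose probe set may also read the related interferon gene Isg15. Of 33 interferon response genes, 19 fell by 24 h and 23 by 48 h, and none rose (26 and 30 down when adjusted over the list alone). The medians were -0.39 (camera adjusted p = 3.06e-58, adjusted p = 0.0891 with an estimated correlation) and -0.53 (adjusted p = 3.07e-64, adjusted p = 0.0719 with an estimated correlation). Beside this group, untreated 18S log2 signal went from 6.84 and 7.0 at 0 h to 7.48 and 6.3 at 24 h and 5.78 and 5.53 at 48 h.

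**Figure D4:**
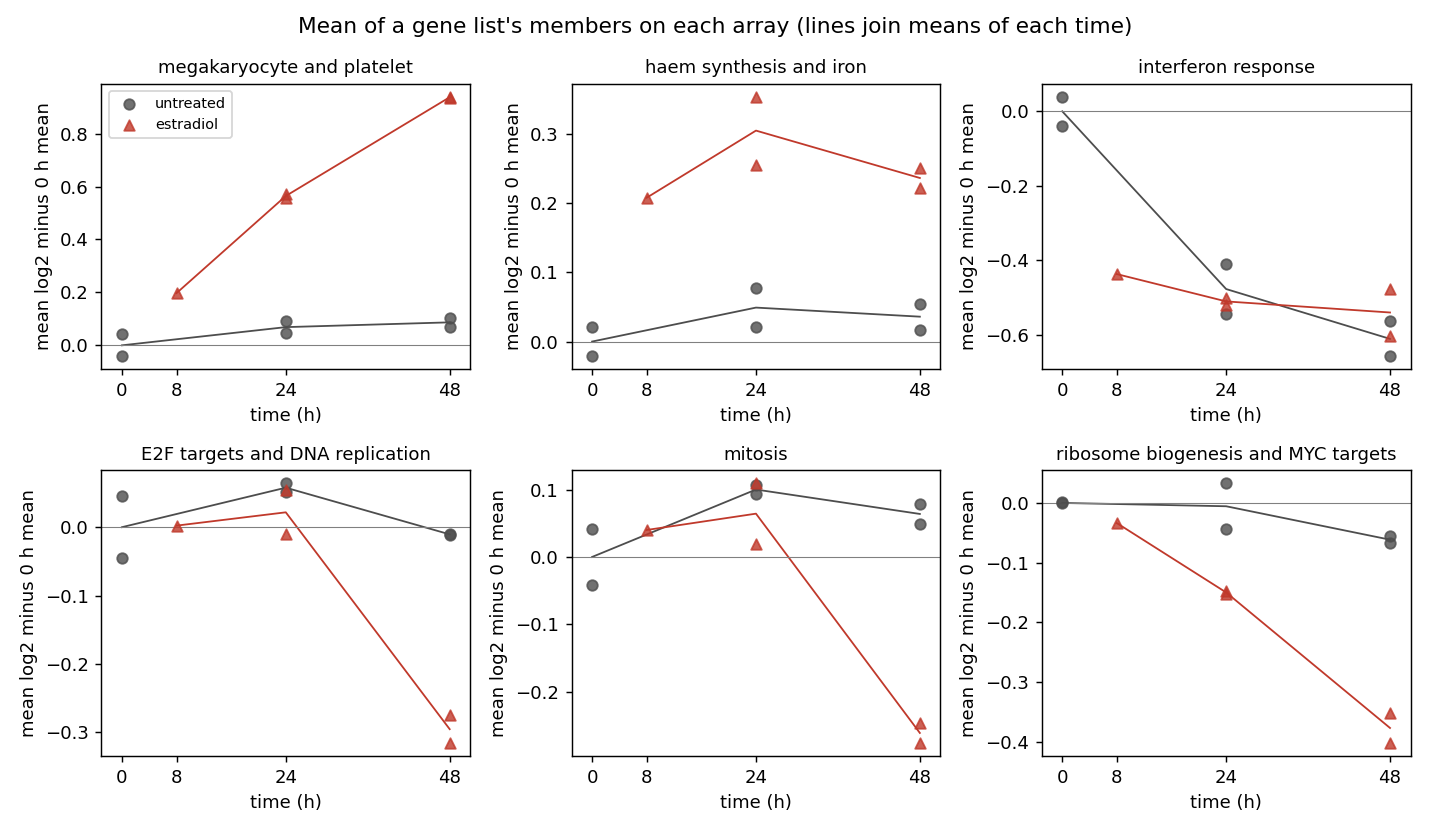
Mean log2 value of the members of 6 gene lists on each array, relative to the 0 h mean, against hours, with untreated cells as circles, estradiol-treated cells as triangles and lines joining the means of each time. Interferon response genes lay below their 0 h level in treated and untreated cells alike, with a mean of -0.61 in untreated cells at 48 h. The megakaryocyte and platelet list rose in treated cells.

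Rises of single genes in untreated cells were fewer than falls. H3f3b, a histone variant gene read here by a dim probe set, went from 16.6 ± 10.8 to 141 ± 5.87 at 24 h (2.31 ± 0.19) and 55.8 ± 8.55 at 48 h (1.17 ± 0.19). At 24 h Il4i1 (0.91 ± 0.19), Spred1 (0.58 ± 0.13), the cell cycle inhibitor gene Cdkn2d (0.46 ± 0.087) and Tspoap1 (0.45 ± 0.097) rose, although Spred1 had the opposite sign with the mean of its probe sets (-0.049). At 48 h Capn5 (1.09 ± 0.23), Caln1 (1.02 ± 0.24), Acot6 (0.99 ± 0.23) and 1700094D03Rik (0.91 ± 0.12) rose. Progenitor regulators had 1 of 29 genes up at 24 h and 3 at 48 h (5 and 6 when adjusted over the list alone), Kit and Lmo2 among the latter (adjusted p = 8.19e-05 and 0.000228, adjusted p = 0.2 and 0.15 with an estimated correlation). The megakaryocyte and platelet list had none up at 24 h and 3 at 48 h, Pf4 and Ppbp among them (3 at 24 h, and 5 up and 2 down at 48 h, when adjusted over the list alone). Its adjusted p was 0.0109 and 0.0067, with adjusted p = 0.296 and 0.195 at an estimated correlation. Mitosis genes had none called at either time by either count, with medians of 0.11 and 0.10 (adjusted p = 4.84e-05 and 0.009, adjusted p = 0.296 and 0.421 with an estimated correlation).

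By limma, 70 genes were called in untreated cells at 24 h, 10 higher and 60 lower, and 160 at 48 h, 37 higher and 123 lower. A prior that ignores the intensity trend left 1 and 13. Leaving out a single array gave, at 24 h, 18 without replicate 1 and 40 without replicate 2 of 0 h, and 27 without replicate 2 of 24 h, and at 48 h, 76 without replicate 1 and 105 without replicate 2 of 0 h, and 83 without replicate 2 of 48 h.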

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

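The tests of a fault in the 0 h arrays, of the 18S signal, of a rise in untreated cells and of other estrogen receptors were chosen after the results were seen, while the matched random lists and the other splits of the arrays were chosen before.

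The estradiol effect differed between 48 h and 24 h, by a test of the difference itself, for 54 genes. The 5 largest upward differences were in the platelet genes Ppbp (1.88) and Itgb3 (1.57), Grm2 (1.42), Syngr1 (1.26) and the chemokine gene Cxcl3 (1.17). The 5 largest downward were in Large2 (-1.53), Fgfr4 (-1.04), Usp31 (-0.77), the nucleolar gene Lyar (-0.59) and Cdca7 (-0.57). Other probe sets of Syngr1, Fgfr4 and Usp31 above the intensity filter did not show these differences. Median differences of lists that passed were 0.21 for megakaryocyte and platelet, -0.29 for E2F targets and DNA replication, -0.24 for mitosis and -0.17 for ribosome biogenesis and MYC targets. The first had adjusted p = 0.0392 and the other 3 each adjusted p = 0.0868 with an estimated correlation. The medians were 0.12 for interferon response (adjusted p = 0.664 with an estimated correlation), 0.13 for oestrogen response (adjusted p = 0.15 with an estimated correlation) and 0.25 for immediate early and stress (adjusted p = 0.0868 with an estimated correlation). Of 6062 probe sets without a single gene symbol, which the gene comparisons leave out, 55 differed with estradiol at 24 h (34 higher and 21 lower) and 262 at 48 h (145 higher and 117 lower).

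Interferon response genes were lower in untreated cells at 24 h and 48 h than at 0 h, with adjusted p = 0.0891 and 0.0719 with an estimated correlation. Carry-over of ribosomal RNA, read from 18S, was argued against as the whole cause, since the 18S prediction plus 2 standard errors reached a share of 0.0148 of it at 24 h and 0.474 at 48 h. A fault of the 0 h arrays alone cannot be told apart from a change of the cells: the list fell further between untreated 24 h and 48 h, by a median of -0.12 with 28 of 33 genes lower, but that step had p = 0.16 with an estimated correlation. No biological explanation was tested.

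The replication, mitosis and ribosome lists were lower with estradiol at 48 h, with adjusted p = 0.105, 0.0791 and 0.0417 with an estimated correlation. Intensity-dependent scaling was argued against by random lists matched in intensity, of which 0 of 10000 fell as far for each of the 3 lists, the lowest reaching -0.14, -0.17 and -0.19. A rise in untreated cells between 24 h and 48 h was argued against as well. The share that untreated cells made up of the difference between the 48 h and 24 h effects was highest for mitosis at -0.125. With 2 standard errors added it was highest for ribosome biogenesis at 0.125. A rise in untreated cells before 24 h was not covered by that share. Treated cells fell between those times by medians of -0.35 for E2F targets, -0.31 for mitosis and -0.24 for ribosome biogenesis, against -0.058, -0.047 and -0.056 in untreated cells. Slower proliferation of cells with active full-length GATA1 may account for the pattern, a hypothesis drawn from these arrays that was not tested and that cell counts or DNA content at both times would test.

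Estradiol changed 848 genes when the 4 treated arrays of 24 h and 48 h were set against the 4 untreated ones. Of the 35 splits of the 8 arrays into equal groups, 1, the real one, gave as many, and the highest other count was 1. These counts cannot exclude chance, because every other split has treated and untreated arrays in both groups. A treatment effect then widens the spread within groups and lowers the count. The labels do not say that replicates came from separate cultures, so chance between cultures was not tested. Estradiol acting through receptors other than the fusion protein cannot be told apart from action through it, because no treated cells without the fusion were analysed here. Nor do the labels say which arrays had IL3 and which Tpo, so a difference in cytokine stays open and untested. The oestrogen response list had a median of -0.040 at 24 h and 0.10 at 48 h with members moving both ways, which decides nothing, and Greb1 fell.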

How the results depend on the processing

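Of the results for named genes under the alternatives set beforehand, 5679 stayed the same, 379 were weaker, 25 stronger, 141 moved and 2 reversed. Of the counts of called genes, called lists and shared genes, 78 stayed within 1.5 times and 37 moved further. Of list medians 527 stayed, 11 were weaker, 12 stronger and 10 moved. Of the 47 named genes called at 24 h 33 never lost their call, and of the 87 at 48 h 53 never did, against 1 of 10 and 4 of 10 in untreated cells at 24 h and 48 h. Of the 22 at 8 h and the 15 that differed between times, limma kept 0 through every alternative. The cause of these changes was not tested.

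With a prior that ignores the intensity trend, limma called 190 genes at 24 h, 620 at 48 h, 0 at 8 h, 0 for the difference between times, 1 and 13 in untreated cells at 24 h and 48 h, and 468 over both times. The counts of 0 stood beside 1030 and 1246 genes at an unadjusted p under 0.05, where chance alone would give 0.05 of the 14388 tested. With quantile normalization 82 genes differed between times. With the mean of all probe sets of a gene, 18 did and 78 were called at 8 h, while Mdm2 at 48 h (-0.068) and Spred1 in untreated cells at 24 h (-0.049) turned direction. With an estimated correlation, camera called 1 list at 24 h, 2 at 48 h, 0 at 8 h, 1 for the difference, 0 and 0 in untreated cells at 24 h and 48 h, and 0 over both times, where the preset correlation gave 7, 7, 5, 7, 7, 8 and 9. With a 2-fold change required, 32 genes were shared by 24 h and 48 h and 5 by 8 h and 24 h.

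Leave-one-out counts ranged from 257 (without estradiol 24 h replicate 2) to 338 at 24 h, from 808 to 899 at 48 h, from 51 (without control 0 h replicate 1) to 114 at 8 h and from 16 (without estradiol 48 h replicate 1) to 47 for the difference. They ranged from 561 (without estradiol 48 h replicate 1) to 1114 over both times, and in untreated cells from 18 to 60 at 24 h and from 76 to 115 at 48 h, the lowest of both without control 0 h replicate 1. A group left with a lone array was assumed to vary like the others, and leaving out the lone 8 h array gives no value. Deviations of replicates with the same number correlated at -0.12 to 0.052 over 10 pairs of groups. With the replicate number as a paired block, counts were 408 at 24 h, 1439 at 48 h, 61 for the difference, 77 and 160 in untreated cells and 749 over both times. The 8 h effect has no block value because its array carries no number.

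Added after the data were seen, the 8 h array against untreated 24 h arrays gave 54 genes (37 higher and 17 lower), of which 33 and 8 were shared with the comparison against 0 h, and Ifit1 (0.14) and Usp18 (0.066) turned direction. Fits without the 0 h and 8 h arrays, also added, gave 386 genes for the estradiol effect at 24 h and 1400 for the estradiol effect at 48 h.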

Other observations

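Several genes of the lists that fall outside the naming rule, chosen after their values were seen, moved with estradiol. Id2, an inhibitor of basic helix-loop-helix factors, rose by 1.09 at 24 h and 1.43 at 48 h. The platelet granule protein gene Mmrn1 rose by 0.62 and 1.35, the thrombin receptor gene F2r by 0.77 and 1.0, and the homeobox gene Meis1 by 0.35 and 0.54. The platelet ATP receptor gene P2rx1 rose by 1.26 at 48 h.

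Gene families read from the start of their symbols, 16 in all and added after the data were seen, gave further shifts at 48 h, none of which held with an estimated correlation. Nuclear pore genes fell in 6 of 19 cases and rose in none, with Nup210 at -0.68 and Nup205 at -0.44 and a median of -0.23 (camera adjusted p = 7.72e-06, adjusted p = 0.097 with an estimated correlation). Vacuolar ATPase genes rose in 5 of 20 cases, among them Atp6v1d (0.34) and Atp6v1a (0.30), with a median of 0.17 (adjusted p = 0.00232, adjusted p = 0.12 with an estimated correlation). Autophagy genes rose in 5 of 22 cases, with Gabarapl1 at 1.07 and Map1lc3a at 0.46 (adjusted p = 0.00115, adjusted p = 0.156 with an estimated correlation). Mitochondrial ribosomal protein genes had a median of -0.12 over 76 genes (adjusted p = 0.000253, adjusted p = 0.407 with an estimated correlation). Proteasome genes had a median of -0.12 over 38 genes (adjusted p = 0.00115, adjusted p = 0.407 with an estimated correlation), and 16 aminoacyl-tRNA synthetase genes had a median of -0.15 (adjusted p = 0.0011, adjusted p = 0.294 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.0057 over 42 genes (adjusted p = 0.932). None of the 16 families passed at 24 h, where the smallest adjusted p was 0.1.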
